A study of Rattus norvegicus with 172 samples.

How the data were processed

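The authors hybridised the RNA to Affymetrix rat expression arrays and, per the labels, processed them with Affymetrix Expression Console and RMA. The versions are not given in the sources used here. The deposited table holds log2 RMA values of 31099 probe sets for all arrays, from 2.6 to 15.0. Array medians lay between 7.10 and 7.25 and no quantile varied over arrays by an SD above 0.091, so the values were used as they stand. RMA draws low signals together and equalises the arrays, so small differences near background are compressed and a shift of all genes in one sample would not be seen. RNA of injured cord was pooled from 4 animals per array. P-values therefore measure the spread between pools, and the number of arrays limits the precision.

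Of the probe sets 20832 carry 1 gene symbol, 436 carry several and 9831 were not used because the annotation used here does not list them. Those with 1 symbol, of which the rat gene table holds 20764, gave 14218 genes, 4526 of them with more than 1 probe set. A gene was represented by its probe set with the highest mean over the cord arrays. Genes were tested where the mean of at least 1 group in the fit reached the 40th percentile of all probe set values on the cord arrays (6.55). Rostral, lesion and caudal arrays were fitted apart, each with the normal cord arrays, with 1 mean per arm and day. limma (lmFit, contrasts averaging the days, eBayes) gave the p-values, adjusted by Benjamini and Hochberg within each of 22 comparisons, with a threshold of 0.05. On data simulated at these group sizes, 39 to 100% of genes changed by 0.5 log2 and 81 to 100% of those changed by 1 log2 were called with the right sign.

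Before the data were examined, 31 lists of cell types and processes were fixed (527 entries, 461 matched). camera tested each list with a preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation. Counts adjusted over the list alone use the members' own p-values. Alternatives fixed then were no dim filter, a second quantile normalization, an eBayes trend with robust prior, array weights, a replicate block, only the groups in the contrast, the mean of all probe sets, a 2-fold minimum and leaving out each array in turn. Genes named singly were chosen by a rule fixed at the same time: in each comparison the 6 called genes with the largest rise and the 6 with the largest fall among those with day means on one side on every day, in each list the 4 called members with the largest change, and all members of the neurotrophin list.

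Comparisons between arms share each arm's arrays and are not independent. Day 60 is in the sample labels although the design text leaves it out. 1 lesion group is numbered 2, 3 and 5, and the numbers were taken as names of arrays. Scan dates and animal batches were not used here. On the 5 reference RNA arrays the median technical SD was 0.121, and within groups of 3 it was 0.145 rostral, 0.157 in the lesion, 0.147 caudal and 0.147 in normal cord. The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.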

Results

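The spinal cord of rats was cut in the thoracic region and a 5 mm piece was taken out. The gap received a chitosan tube loaded with NT-3 (NT-3 tube), an empty chitosan tube (tube alone) or nothing (lesion control). The arrays cover the 5 mm segments rostral and caudal to the gap on days 1, 3, 10, 20, 30, 60 and 90, and the lesion segment from day 3 on. Each array of injured cord holds RNA pooled from 4 animals, and there are 3 arrays per group, 2 for tube alone rostral on day 10. The arrays comprise 164 of injured cord in 55 groups, 3 of normal cord and 5 technical replicates of a universal reference RNA. Tube alone is present in the lesion segment on day 3 only, so its lesion comparisons rest on that day. Comparisons over all days are averages, and single days can run the other way. Arrays of one group had a median correlation of 0.9931, and the lowest group value was 0.9724. Changes below are log2 differences with standard errors, and a gene is said to rise or fall where its adjusted p is under 0.05.

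An MHC class I gene, RT1-CE10, divided the groups by arm and day, though not alike in all segments. In the rostral segment its mean was 10.79 ± 0.51 (SD, n = 3) in NT-3 tube on day 1, 11.23 ± 0.05 on day 30 and 10.90 ± 0.48 on day 90, against 7.38 ± 0.03 on day 10 and 7.23 ± 0.07 on day 60. In tube alone it was high on day 1 (10.82 ± 0.17), day 30 (10.96 ± 0.13) and day 60 (10.42 ± 0.52). In lesion control it was high on day 30 (10.95 ± 0.20) and low on day 1 (6.71 ± 0.07) and day 90 (7.23 ± 0.15). The same days were high in the caudal segment, for example 10.91 ± 0.65 in NT-3 tube and 7.09 ± 0.07 in lesion control on day 90. On day 20 the NT-3 tube and lesion control differed by 2.58 in the lesion, 0.50 rostral and 0.28 caudal. A second class I gene, RT1-CE12, followed: 12.10 ± 0.20 and 10.57 ± 0.02 rostral on day 90. Arms are therefore also compared over the days on which the arms' RT1-CE10 means differed by less than 1 log2 unit, called matched days below.

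**Figure D1:**
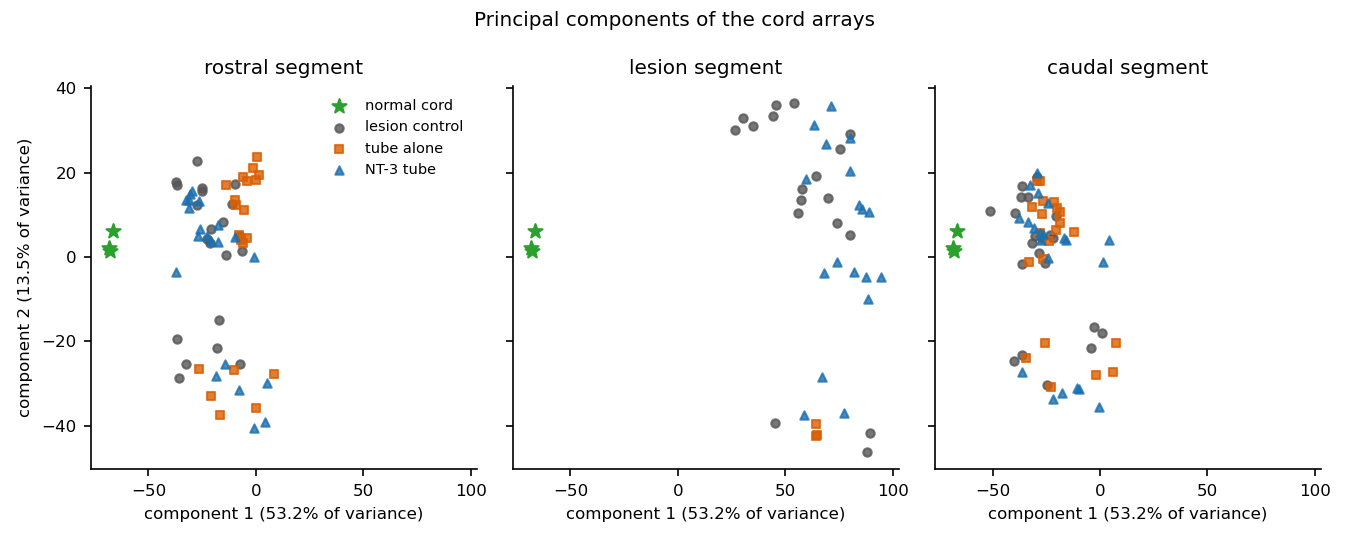
First 2 principal components of the cord arrays, split by segment and arm. The first component holds 53.2% of the variance.

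Rostral to the gap, days 1-3 in lesion control (6 arrays) against normal cord (3) brought rises of inflammatory, astrocyte and matrix genes and falls of neuronal genes. Ccl2, the chemokine that draws monocytes, rose by 6.08 ± 0.26 (67.4-fold), LPS-binding protein Lbp (5.34 ± 0.27), and the metalloproteinase inhibitor Timp1 (5.06 ± 0.18) and hyaluronan-binding Tnfaip6 (5.02 ± 0.20) rose with the astrocyte-reaction genes Lcn2 (4.80 ± 0.39) and Serpina3n (4.75 ± 0.33). Among reactive astrocyte genes 13 of 13 rose, and among microglia and macrophage genes 19 of 21, with Cd14 (3.95 ± 0.18) and Gpnmb (3.79 ± 0.11). These had camera adjusted p = 7.72e-13 and 1.14e-14, and adjusted p = 0.00152 and 0.00705 with an estimated correlation. Cytokine and chemokine genes rose in 16 of 20, among them Ccl7 (4.51 ± 0.25), Cxcl1 (3.97 ± 0.40) and Il6 (3.67 ± 0.31) (camera adjusted p = 1.44e-06, adjusted p = 0.23 with an estimated correlation). Of the complement genes 7 of 8 rose, of the interferon response genes 13 of 16, and of the immediate early genes 8 of 9, with the injury factor Atf3 (3.94 ± 0.16). The tests gave camera adjusted p = 5.43e-05, 0.000136 and 2.96e-06, and adjusted p = 0.166, 0.315 and 0.169 with an estimated correlation. All 21 cell cycle genes rose, Cdk1 (3.24 ± 0.18) and Mki67 (2.86 ± 0.28) included, as did 23 of 24 fibroblast and fibrillar matrix genes with Lox (3.95 ± 0.38) and Thbs2 (3.19 ± 0.18). The lists had camera adjusted p = 2.05e-14 and 8.06e-10, and adjusted p = 0.142 and 0.275 with an estimated correlation. Of the neuron genes 17 of 19 fell, among them NeuN, Rbfox3 (-1.29 ± 0.27), and of the synaptic transmission genes 20 of 22, among them the GABA-A subunit Gabrb2 (-1.18 ± 0.18). The list tests gave camera adjusted p = 7.69e-05 and 6.78e-07, and adjusted p = 0.379 and 0.22 with an estimated correlation. The astrocyte amino-acid transporter Slc7a10 (-1.59 ± 0.16) and mitochondrial glutamate carrier Slc25a18 (-1.59 ± 0.18) fell, as did Klhdc7a (-1.96 ± 0.18), Hhatl (-1.73 ± 0.15), Hoxd9 (-1.66 ± 0.33) and Adam11 (-1.62 ± 0.15). Myelin and sterol genes fell too: 11 of 15 oligodendrocyte and central myelin genes, ermin Ermn (-1.13 ± 0.13) included, and 14 of 16 cholesterol synthesis genes, with Mvd (-0.83 ± 0.10). As lists they had camera adjusted p = 0.0011 and 0.000357, and adjusted p = 0.329 and 0.286 with an estimated correlation. Regeneration-associated genes went both ways, 13 up and 5 down of 21 (camera adjusted p = 0.00315, adjusted p = 0.271 with an estimated correlation). Of 18 growth-inhibitory matrix and guidance genes 11 fell and 2 rose (camera adjusted p = 0.022, adjusted p = 0.22 with an estimated correlation). The ependyma and cilia list was not called, with 6 of 7 genes lower (camera adjusted p = 0.0695), nor was the oligodendrocyte precursor list (2 up, 4 down of 9, camera adjusted p = 0.7). Adjusted over the list alone, these counts were the same, except for cytokine and chemokine genes (17 that rose), fibroblast and fibrillar matrix genes (24 that rose) and cholesterol synthesis genes (15 that fell). Overall 3343 of 11553 genes rose and 3474 fell, 821 and 186 of them at least 2-fold.

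On days 10-30 the rostral segment (9 arrays against 3) held high levels of phagocyte genes. The Fc-receptor-like gene Fcrl2 (5.66 ± 0.17), macrophage elastase Mmp12 (5.23 ± 0.52), dectin-1 Clec7a (5.10 ± 0.19), Gpnmb (4.92 ± 0.11), Lilrb4 (4.96 ± 0.47) and Ifitm1 (5.10 ± 0.28) rose. All 21 microglia and macrophage genes rose, all 9 MHC class II presentation genes, with RT1-Bb (3.02 ± 0.67), and all 19 lysosome and lipid handling genes. Here camera adjusted p was 1.97e-18, 2.21e-05 and 1.81e-12, and adjusted p = 0.00271, 0.169 and 0.0711 with an estimated correlation. Complement genes rose in 8 of 8, with the C1 inhibitor Serping1 (3.09 ± 0.09), interferon response genes in 15 of 16 and cytokine and chemokine genes in 17 of 20, led by the B-cell chemokine Cxcl13 (3.16 ± 0.42). For these lists camera adjusted p was 3.81e-06, 5.7e-06 and 9.66e-05, and adjusted p = 0.113, 0.242 and 0.321 with an estimated correlation. All 24 fibroblast and fibrillar matrix genes rose, periostin Postn (4.40 ± 0.39) among them, and all 13 reactive astrocyte genes (camera adjusted p = 7.72e-13 and 8.29e-09, and adjusted p = 0.22 and 0.00705 with an estimated correlation). The growth factor Igf1 (2.83 ± 0.18) rose. All 16 cholesterol synthesis genes fell (camera adjusted p = 1.46e-11, adjusted p = 0.0569 with an estimated correlation), beside the desaturase Scd (-2.39 ± 0.12, 5.23-fold). Neuron genes fell in 18 of 19, NeuN, Rbfox3 (-1.91 ± 0.25), among them, and synaptic transmission genes in 21 of 22 (camera adjusted p = 2.29e-07 and 6.07e-09, and adjusted p = 0.259 and 0.169 with an estimated correlation). The neuronal exchange factor Rapgef4 (-2.07 ± 0.12), Klhdc7a (-1.98 ± 0.17), and the positional homeobox genes Hoxd9 (-1.89 ± 0.31) and Hoxa10 (-1.88 ± 0.31) fell. The T-cell gene Cd8a (2.69 ± 0.27) rose while the lymphocyte list was not called (6 of 8 genes rose, camera adjusted p = 0.0553). Sensory ganglion genes in this segment included Calca (1.63 ± 0.28) and advillin Avil (1.46 ± 0.39), higher in lesion control, in a list that was not called (3 of 8 rose, camera adjusted p = 0.336). The same counts passed when adjusted over the list alone, except for interferon response genes (16 that rose) and sensory ganglion genes (2 that rose). Of 11553 genes 3545 rose and 3741 fell, 1017 and 426 at least 2-fold.

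By days 60-90 rostral (6 arrays against 3), lysosomal and sterol genes were changed. Fcrl2 (5.62 ± 0.18), Clec7a (5.38 ± 0.20), Gpnmb (5.15 ± 0.11), the lysosomal marker Cd68 (4.98 ± 0.20), Plbd1 (4.63 ± 0.28) and Apobec1 (4.60 ± 0.18) rose. All 19 lysosome and lipid handling genes rose, cathepsin K Ctsk (3.70 ± 0.26) and the cholesterol exporter Abca1 (2.65 ± 0.12) included, and all 21 microglia and macrophage genes. In this order camera adjusted p was 1.15e-15 and 1.09e-20, and adjusted p = 0.0321 and 0.00152 with an estimated correlation. All 16 cholesterol synthesis genes fell, among them Idi1 (-1.97 ± 0.12), Hsd17b7 (-1.83 ± 0.11) and Mvd (-1.70 ± 0.10) (camera adjusted p = 3.28e-14, adjusted p = 0.0257 with an estimated correlation), beside Scd (-2.83 ± 0.13, 7.09-fold). Reactive astrocyte genes rose in 12 of 13 and fibroblast and fibrillar matrix genes in 23 of 24, with lumican Lum (2.23 ± 0.25). By the list test camera adjusted p was 4e-09 and 1.15e-08, and adjusted p = 0.00705 and 0.301 with an estimated correlation. Here neuron genes fell in 18 of 19 and rose in 1, and synaptic transmission genes fell in 18 of 22 (camera adjusted p = 2.21e-05 and 8.69e-07, and adjusted p = 0.35 and 0.22 with an estimated correlation). Hoxd9 (-2.08 ± 0.33) and the G-protein subunit Gng13 (-2.08 ± 0.28) fell. The B-cell gene Ms4a1 (-0.58 ± 0.20) fell. Of the sensory ganglion genes 5 of 8 rose, with Avil (2.35 ± 0.42) (camera adjusted p = 0.0591). Counts adjusted over the list alone did not differ from these, except for synaptic transmission genes (19 that fell). In all 2940 of 11553 genes rose and 3753 fell, 763 and 325 at least 2-fold.

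In the lesion segment on day 3 (3 lesion control arrays against 3 of normal cord), neuronal genes were low. Neuron genes fell in 19 of 19, with a median of -4.25, and synaptic transmission genes in 21 of 22 (camera adjusted p = 1.54e-06 and 1.09e-07, and adjusted p = 0.36 and 0.207 with an estimated correlation). Single falls were Chodl (-5.86 ± 0.51), a motor neuron gene, the sodium channel Scn1a (-5.70 ± 0.65), the serotonin receptor Htr2c (-5.69 ± 0.73), Olfm3 (-5.50 ± 0.38), the calcium sensor Vsnl1 (-5.48 ± 0.73) and mitochondrial creatine kinase Ckmt1 (-5.43 ± 0.54). Oligodendrocyte and central myelin genes fell in 15 of 15, with Ermn (-4.66 ± 0.59) and cholesterol synthesis genes in 16 of 16. These had camera adjusted p = 2.45e-05 and 1.74e-07, and adjusted p = 0.374 and 0.22 with an estimated correlation. Reactive astrocyte genes rose in 12 of 13 and fell in 1 (camera adjusted p = 0.000699, adjusted p = 0.0321 with an estimated correlation). Rises took in Ccl2 (7.03 ± 0.19, 131-fold), the fatty-acid binding protein Fabp4 (7.51 ± 0.26), tenascin N, Tnn (7.21 ± 0.38), Lbp (6.65 ± 0.17), Akr1b8 (6.53 ± 0.22) and Lilrb4 (6.53 ± 0.29). All 24 fibroblast and fibrillar matrix genes rose and all 21 cell cycle genes, with Mki67 (5.60 ± 0.22) (camera adjusted p = 9.58e-13 and 3.13e-12, and adjusted p = 0.11 and 0.0711 with an estimated correlation). Cytokine and chemokine genes rose in 19 of 20, microglia and macrophage genes in 20 of 21, interferon response genes in 16 of 16, with Ifit3 (4.42 ± 0.35), and lymphocyte genes in 10 of 13, with Cd8a (4.93 ± 0.22). The tests gave camera adjusted p = 1.01e-05, 1.31e-07, 5.76e-05 and 0.0184, and adjusted p = 0.148, 0.18, 0.275 and 0.436 with an estimated correlation. Gelatinase B, Mmp9 (4.74 ± 0.47), rose while the neutrophil list was not called (8 of 9, camera adjusted p = 0.0527). Skeletal muscle genes moved with these: 9 of 16 rose, myosin light chain Myl1 (4.55 ± 1.26) among them (camera adjusted p = 0.429). The muscle list of the 3 lesion control arrays stood at 0.41, 4.36 and 1.44 against normal cord. With p-values adjusted over the list alone, the counts stayed the same. Of 11922 genes 5044 rose and 4144 fell, 2378 and 2027 at least 2-fold.

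On days 10-30 the lesion segment (9 arrays against 3) had high matrix and low neuronal transcripts. Postn (7.27 ± 0.16, 155-fold), macrophage elastase Mmp12 (7.01 ± 0.18), Lilrb4 (6.53 ± 0.24), Lbp (6.12 ± 0.14) and Ifitm1 (6.04 ± 0.16) rose, with all 24 fibroblast and fibrillar matrix genes and 8 of 9 complement genes. The lists had camera adjusted p = 4.78e-16 and 0.000123, and adjusted p = 0.0556 and 0.169 with an estimated correlation. Schwann cell and peripheral myelin genes rose in 8 of 9, the transcription factor Egr2 (3.37 ± 0.15) and the low-affinity neurotrophin receptor Ngfr (2.65 ± 0.24) among them (camera adjusted p = 0.0344, adjusted p = 0.394 with an estimated correlation). Reactive astrocyte genes rose in 11 and fell in 1 of 13 (camera adjusted p = 0.000442, adjusted p = 0.0257 with an estimated correlation). Skeletal muscle genes moved with the matrix, 14 up and 1 down of 16, with Myl1 (6.21 ± 1.03, 74.2-fold) (camera adjusted p = 0.0772). Cartilage and bone genes rose in 8 of 10, bone sialoprotein Ibsp (4.41 ± 0.54) among them (camera adjusted p = 0.0703), adipocyte genes in 4 of 4, adipsin Cfd (4.21 ± 0.20) among them (camera adjusted p = 0.229), and sensory ganglion genes in 5 of 9, with Avil (2.67 ± 0.39) (camera adjusted p = 0.473). Here neuron genes fell in 19 of 19 and synaptic transmission genes in 21 of 22 (camera adjusted p = 1.69e-05 and 3.73e-08, and adjusted p = 0.404 and 0.195 with an estimated correlation). Genes of inhibitory neurons were among them: GABA synthesis by Gad1 (-5.37 ± 0.41) and the vesicular GABA transporter Slc32a1 (-5.10 ± 0.28), beside Htr2c (-6.06 ± 0.59), Olfm3 (-5.46 ± 0.31), Scn1a (-5.22 ± 0.53) and the potassium channel Kcnc1 (-5.20 ± 0.38). Adjusted over the list alone, these counts were the same. In total 4973 of 11922 genes rose and 4315 fell, 2009 and 1743 at least 2-fold.

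The lesion segment of days 60-90 (6 arrays against 3) combined matrix and muscle transcripts with low neuronal ones. All 24 fibroblast and fibrillar matrix genes rose (camera adjusted p = 1.33e-17, adjusted p = 0.0364 with an estimated correlation). Mmp12 (6.55 ± 0.19), the lymphoid chemokine Ccl21 (6.43 ± 0.29) and Gdf10 (5.90 ± 0.18) rose. Skeletal muscle genes rose in 14 of 16 (camera adjusted p = 0.0185, adjusted p = 0.656 with an estimated correlation), with Myl1 (6.14 ± 1.09), myosin heavy chain Myh2 (5.54 ± 1.01) and Myl11 (5.49 ± 1.04). Sensory ganglion genes moved with them, 6 of 9 up, with Avil (3.80 ± 0.42) and the sodium channel of nociceptors Scn11a (2.82 ± 0.42) (camera adjusted p = 0.0878). Endothelium and angiogenesis genes rose in 14 of 20 and fell in 2, reactive astrocyte genes rose in 12 of 13 (camera adjusted p = 0.00884 and 5.31e-05, and adjusted p = 0.373 and 0.00926 with an estimated correlation). Neuron genes fell in 16 of 19, synaptic transmission genes in 21 of 22 and cholesterol synthesis genes in 16 of 16 (camera adjusted p = 0.000459, 1.91e-07 and 3.73e-08, and adjusted p = 0.498, 0.216 and 0.207 with an estimated correlation). Olfm3 (-4.55 ± 0.33), Slc32a1 (-4.53 ± 0.29), Htr2c (-4.34 ± 0.63), Kcnc1 (-4.33 ± 0.40), Gad1 (-4.11 ± 0.44) and the GABA-A subunit Gabra5 (-4.09 ± 0.22) fell. The same counts passed when adjusted over the list alone, except for neuron genes (17 that fell). Of 11922 genes 4243 rose and 4365 fell, 1668 and 1481 at least 2-fold.

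**Figure D2:**
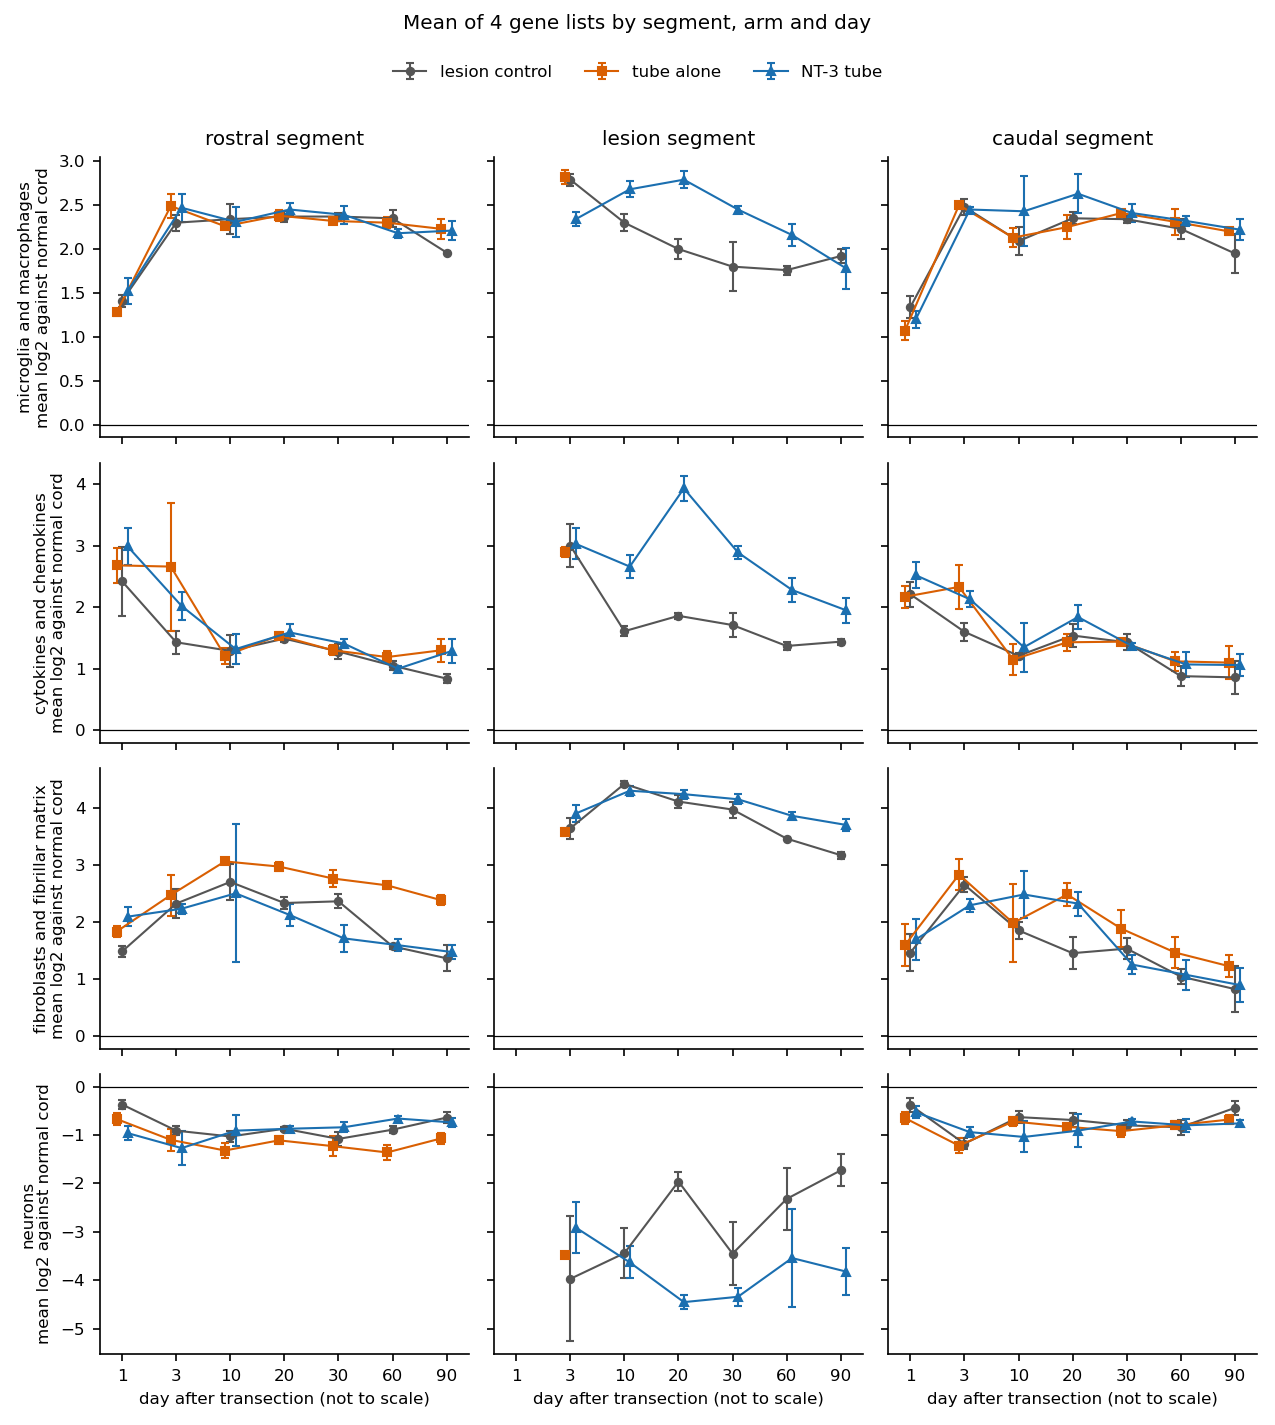
Mean log2 level against normal cord of 4 fixed gene lists by day, arm and segment, with standard deviations over arrays. Each point has 3 arrays, 2 for tube alone rostral on day 10.

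Caudal to the gap, days 1-3 in lesion control (6 arrays against 3) raised Ccl2 by 6.30 ± 0.36, Lbp (5.55 ± 0.32), Timp1 (5.29 ± 0.20), Lcn2 (5.23 ± 0.38), Serpina3n (5.06 ± 0.27) and the leukocyte protease inhibitor Slpi (4.92 ± 0.32). Reactive astrocyte genes rose in 13 of 13 (camera adjusted p = 1.17e-11, adjusted p = 0.0048 with an estimated correlation). Microglia and macrophage genes rose in 19 and fell in 1 of 21, cell cycle genes rose in 21 of 21, fibroblast and fibrillar matrix genes in 23 of 24. The list tests gave camera adjusted p = 1.87e-12, 2.27e-15 and 4.75e-10, and adjusted p = 0.0711, 0.0817 and 0.259 with an estimated correlation. Here neuron genes fell in 19 of 19 and synaptic transmission genes in 20 of 22 (camera adjusted p = 3.87e-06 and 1.12e-06, and adjusted p = 0.291 and 0.233 with an estimated correlation). Klhdc7a (-2.28 ± 0.19), Adam11 (-1.70 ± 0.15), Slc25a18 (-1.69 ± 0.18), the calmodulin kinase subunit Camk2g (-1.65 ± 0.23), Slc7a10 (-1.64 ± 0.17) and Pnma8b (-1.64 ± 0.43) fell. Counts adjusted over the list alone did not differ from these. Of 11479 genes 3537 rose and 3492 fell, 904 and 307 at least 2-fold.

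On days 10-30 caudal (9 arrays against 3), Fcrl2 (5.76 ± 0.16), Clec7a (4.88 ± 0.17), Gpnmb (4.67 ± 0.12), Cxcl13 (4.54 ± 0.41), Cd68 (4.53 ± 0.24) and Ifitm1 (4.51 ± 0.31) rose. So did all 21 microglia and macrophage genes, all 19 lysosome and lipid handling genes, all 24 fibroblast and fibrillar matrix genes and all 13 reactive astrocyte genes. As lists they had camera adjusted p = 2.68e-21, 5.24e-13, 1.14e-09 and 2.52e-09, and adjusted p = 0.00821, 0.142, 0.272 and 0.00947 with an estimated correlation. All 16 cholesterol synthesis genes fell (camera adjusted p = 2.05e-14, adjusted p = 0.0364 with an estimated correlation), with Scd (-2.39 ± 0.11, 5.25-fold) and Hsd17b7 (-1.72 ± 0.12). Neuron genes fell in 18 of 19, Rbfox3 (-1.58 ± 0.30) among them, and synaptic transmission genes in 20 of 22 (camera adjusted p = 3.03e-06 and 4.86e-07, and adjusted p = 0.288 and 0.221 with an estimated correlation). Klhdc7a (-1.95 ± 0.18), Rapgef4 (-1.68 ± 0.17) and Slc5a11 (-1.54 ± 0.14) fell. With p-values adjusted over the list alone, the counts stayed the same. In all 3215 of 11479 genes rose and 3366 fell, 810 and 160 at least 2-fold.

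Caudal days 60-90 (6 arrays against 3) had Fcrl2 (5.50 ± 0.17), Clec7a (5.16 ± 0.18), Gpnmb (5.04 ± 0.12), Cd68 (4.88 ± 0.26), Apobec1 (4.50 ± 0.21) and Tnfaip6 (4.45 ± 0.22) above normal cord. Microglia and macrophage genes rose in 20 of 21 and lysosome and lipid handling genes in 19 of 19, with Ctsk (3.18 ± 0.25) and Abca1 (2.71 ± 0.17). Here camera adjusted p was 2.04e-22 and 1.15e-15, and adjusted p = 0.00705 and 0.084 with an estimated correlation. All 16 cholesterol synthesis genes fell, Idi1 (-1.98 ± 0.14) and Hsd17b7 (-1.93 ± 0.13) included (camera adjusted p = 4.1e-16, adjusted p = 0.0249 with an estimated correlation), beside Scd (-2.93 ± 0.11, 7.61-fold). Here neuron genes fell in 18 of 19 (camera adjusted p = 3.25e-05, adjusted p = 0.341 with an estimated correlation), and parvalbumin Pvalb (-1.72 ± 0.27), Gng13 (-1.92 ± 0.33) and semaphorin Sema4d (-1.72 ± 0.15) fell. The growth factor Igf1 (2.06 ± 0.22) rose and the neurotrophin Bdnf (-0.80 ± 0.16) fell, in a neurotrophin and receptor list that was not called (4 up, 1 down of 7, camera adjusted p = 0.227). Reactive astrocyte genes rose in 12 of 13 (camera adjusted p = 3.22e-09, adjusted p = 0.00947 with an estimated correlation). Adjusted over the list alone, these counts were the same. Here 2750 of 11479 genes rose and 3310 fell, 620 and 120 at least 2-fold.

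**Figure D3:**
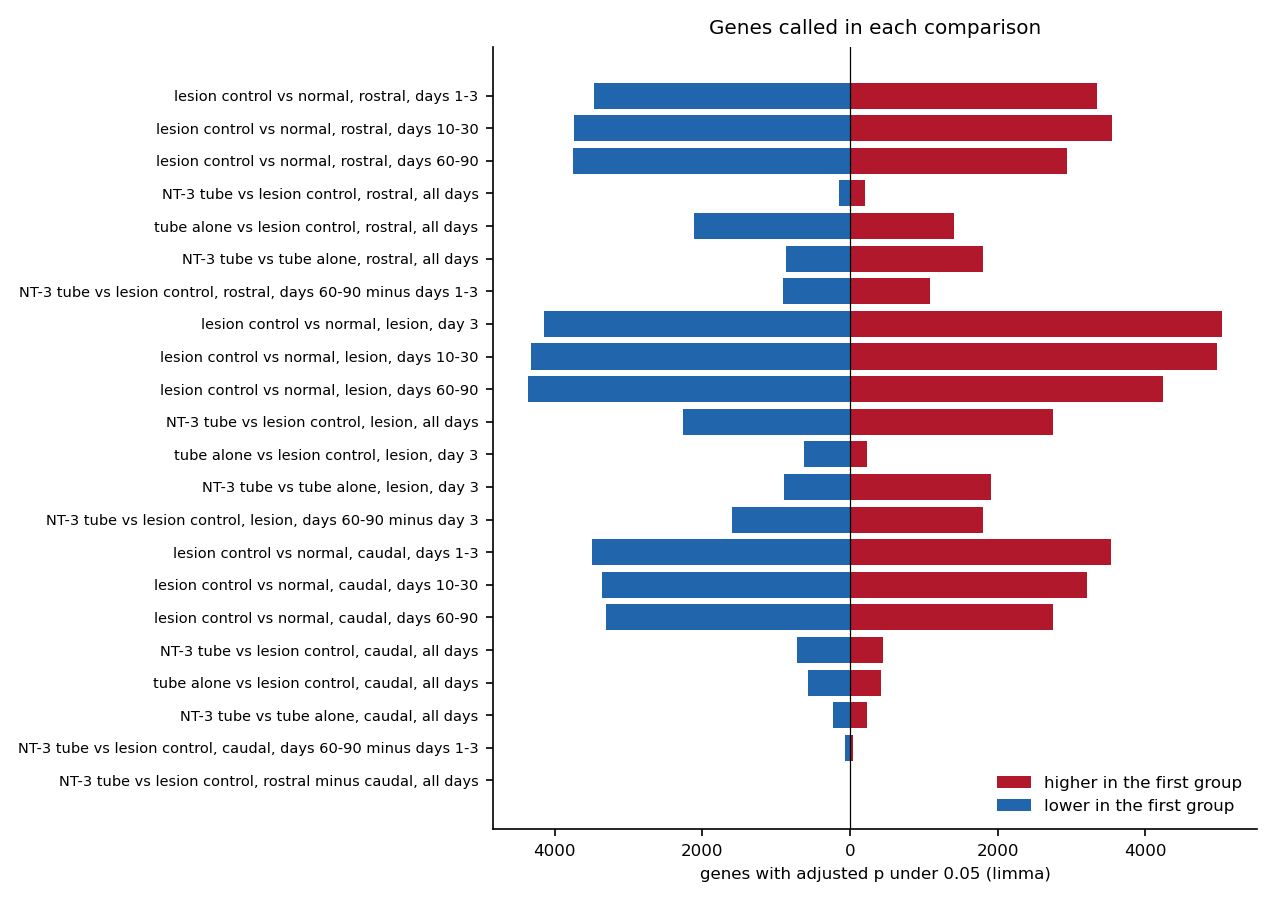
Genes higher and lower past an adjusted p of 0.05 in each comparison. Counts rest on the arrays named with each comparison.

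In the lesion segment over days 3-90 (18 NT-3 tube against 18 lesion control arrays), inflammatory genes were higher with the NT-3 tube on average. Stromelysin-1, Mmp3 (3.40 ± 0.23, 10.6-fold), the chemokines Cxcl2 (2.23 ± 0.17) and Ccl20 (2.07 ± 0.18), Gpr15lg (1.91 ± 0.13), plasminogen activator inhibitor 2 Serpinb2 (1.89 ± 0.15) and complement C6 (1.84 ± 0.11) rose. Of 20 cytokine and chemokine genes 18 rose and 1 fell, with the B-cell chemokine Cxcl13 (2.01 ± 0.19) and Ccl7 (1.91 ± 0.09) beside arginase Arg1 (2.72 ± 0.12). This list had camera adjusted p = 3.03e-12 and adjusted p = 0.0136 with an estimated correlation. Lymphocyte genes rose in 12 of 13, with the T-cell genes Cd3e (1.04 ± 0.09) and Cd5 (1.10 ± 0.11), MHC class II presentation genes in 9 of 9, with RT1-Bb (1.26 ± 0.27), and complement genes in 8 of 9, with C3 (1.73 ± 0.16). For these lists camera adjusted p was 6.75e-08, 1.08e-06 and 1.14e-05, and adjusted p = 0.142, 0.116 and 0.138 with an estimated correlation. Here microglia and macrophage genes rose in 11 and fell in 1 of 21, Cd14 (1.21 ± 0.07) and Itgam (0.97 ± 0.06) up (camera adjusted p = 0.000811, adjusted p = 0.36 with an estimated correlation). Cell cycle genes rose in 17 of 21, with Mki67 (0.53 ± 0.09), fibroblast and fibrillar matrix genes in 16 of 24, with Loxl2 (0.79 ± 0.11), and reactive astrocyte genes in 8 of 13, with Aspg (0.88 ± 0.08), while 1 fell. In this order camera adjusted p was 2.38e-06, 0.000202 and 0.0155, and adjusted p = 0.195, 0.332 and 0.142 with an estimated correlation. The neutrophil list split, with Mmp9 (1.18 ± 0.19) up and S100a8 (-0.95 ± 0.32) down, a median of -0.62 and a mean of -0.2 (camera adjusted p = 0.903). Neuron genes fell in 18 of 19, neurofilament Nefh (-1.45 ± 0.29) among them, synaptic transmission genes in 11 of 22 and motor neuron genes in 5 of 7. By the list test camera adjusted p was 2.5e-08, 0.000594 and 0.00451, and adjusted p = 0.291, 0.381 and 0.259 with an estimated correlation. Sensory ganglion genes moved with them: all 9 fell, with Calca (-1.66 ± 0.30) (camera adjusted p = 1.6e-05, adjusted p = 0.301 with an estimated correlation). Day 3 ran the other way: with the NT-3 tube and in lesion control the neuron list stood at -2.91 ± 0.53 and -3.97 ± 1.29, the ganglion list at 0.46 ± 0.94 and -0.95 ± 0.15, the lymphocyte list at 0.95 ± 0.10 and 1.43 ± 0.22 and the microglia list at 2.34 ± 0.08 and 2.79 ± 0.07 (day 90 1.78 ± 0.23 and 1.92 ± 0.08). All 16 skeletal muscle genes fell, Myl1 (-3.79 ± 0.52), skeletal actin Acta1 (-3.69 ± 0.48), Myl11 (-3.57 ± 0.49), Myh2 (-3.55 ± 0.48), troponin Tnnc2 (-3.37 ± 0.44) and Smpx (-2.46 ± 0.36) among them, and erythrocyte genes in 3 of 4. These had camera adjusted p = 1.56e-10 and 0.0232, and adjusted p = 0.221 and 0.317 with an estimated correlation. Oligodendrocyte and central myelin genes fell in 12 of 15, with Mobp (-1.11 ± 0.20) (camera adjusted p = 0.000185, adjusted p = 0.428 with an estimated correlation). Neural progenitor genes fell in 10 and rose in 3 of 17, doublecortin Dcx (-1.24 ± 0.08) and Sox2 (-0.86 ± 0.10) down (camera adjusted p = 0.012, adjusted p = 0.207 with an estimated correlation). Neurotrophin and receptor genes fell in 5 of 7, with Ngfr (-0.84 ± 0.12), the GDNF receptor Gfra1 (-0.55 ± 0.06) and the BDNF receptor Ntrk2 (-0.58 ± 0.13) (camera adjusted p = 0.0133, adjusted p = 0.262 with an estimated correlation). Endothelium and angiogenesis genes fell in 11, endomucin Emcn (-0.78 ± 0.06) included, and rose in 4 of 20 (camera adjusted p = 0.00347, adjusted p = 0.324 with an estimated correlation). The same counts passed when adjusted over the list alone, except for complement genes (1 that fell), fibroblast and fibrillar matrix genes (2 that fell), reactive astrocyte genes (9 that rose and 3 that fell), neural progenitor and neurogenesis genes (4 that rose) and neurotrophin and receptor genes (1 that rose). Of 11922 genes 2746 rose and 2265 fell, 73 and 142 at least 2-fold. On the 3 matched days (10, 30 and 60) 1753 rose and 1853 fell, and with the sensory ganglion list mean as a covariate 2130 genes passed.

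**Figure D4:**
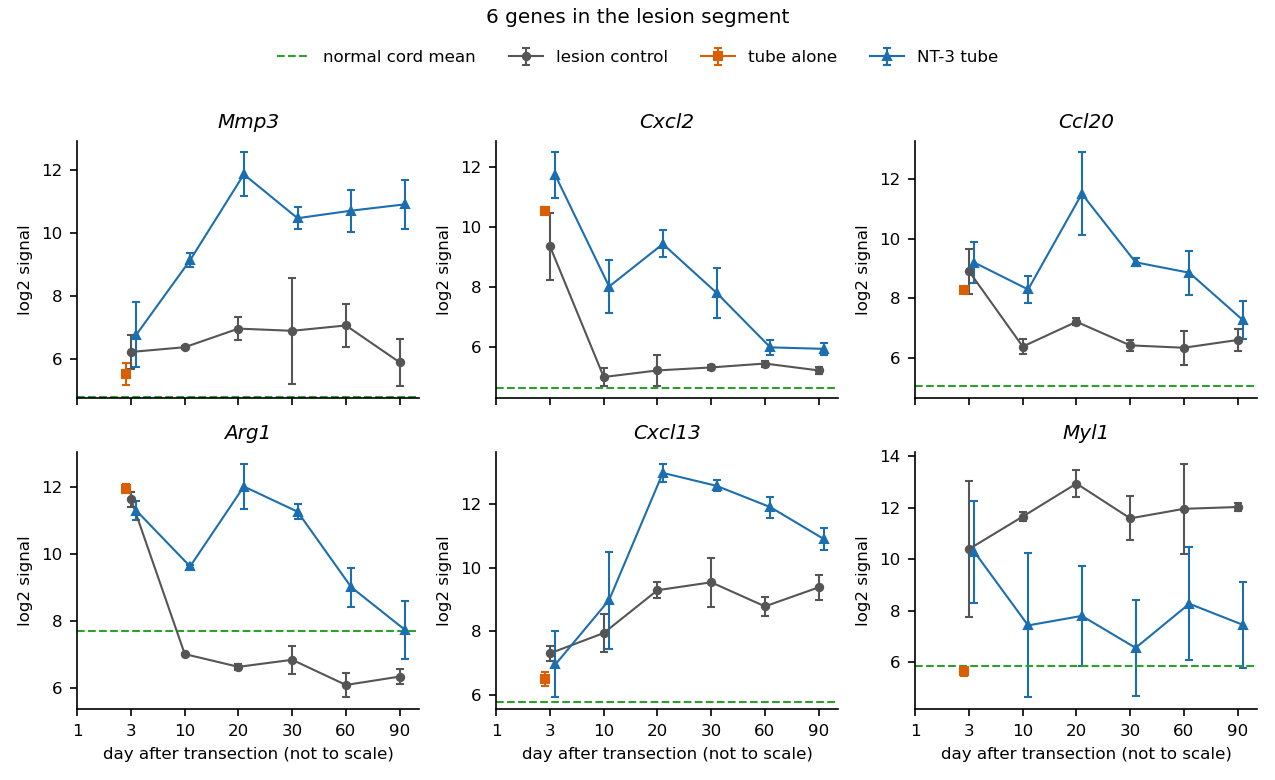
Log2 level of 6 genes in the lesion segment by day and arm, mean and standard deviation, with the normal cord mean dashed. Each point has 3 arrays.

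Rostral, the NT-3 tube and lesion control arms (21 and 21 arrays) differed in few genes, 204 up and 147 down of 11553. The aldo-keto reductase Akr1b7 (0.79 ± 0.20) and class I gene RT1-CE12 (0.61 ± 0.05) rose, with the interferon-induced Oas1b (0.49 ± 0.07), the tryptophan-pathway enzyme Kmo (0.47 ± 0.11), Pmp2 (0.43 ± 0.08) and the receptor Il4r (0.26 ± 0.06). Cytokine and chemokine genes rose in 4 of 20 (13 adjusted over the list alone), Cxcl1 (0.75 ± 0.17), Il6 (0.52 ± 0.13), Ccl2 (0.50 ± 0.11) and Ccl7 (0.47 ± 0.11). The list had camera adjusted p = 1.94e-06 and adjusted p = 0.233 with an estimated correlation. The integrin Itgam (0.23 ± 0.06), the receptor of granulocyte growth factor Csf3r (0.33 ± 0.09) and the T-cell gene Cd3g (0.38 ± 0.10) rose, the last in a lymphocyte list with 1 of 8 (6 adjusted over the list alone). The list test gave camera adjusted p = 0.000242 and adjusted p = 0.148 with an estimated correlation. C6 (0.46 ± 0.10), Arg1 (0.41 ± 0.10), nitric oxide synthase Nos3 (0.41 ± 0.07), endoglin Eng (0.26 ± 0.06) and the replication gene Mcm3 (0.23 ± 0.05) rose. The homeobox genes Hoxa10 (-0.66 ± 0.14) and Hoxa9 (-0.42 ± 0.05) fell, with osteoglycin Ogn (-0.40 ± 0.11), Cytl1 (-0.34 ± 0.07), Ube3al1 (-0.37 ± 0.08) and C11h21orf91 (-0.36 ± 0.10). Bdnf (-0.22 ± 0.06), doublecortin Dcx (-0.21 ± 0.05) and the ephrin receptor Epha4 (-0.22 ± 0.05) fell. Of 12 homeostatic astrocyte genes 0 fell over all genes tested and 4 adjusted over the list alone (camera adjusted p = 0.000355, adjusted p = 0.259 with an estimated correlation). Sensory ganglion genes fell in 0 of 8 (5 adjusted over the list alone) (camera adjusted p = 7.69e-05, adjusted p = 0.271 with an estimated correlation). On the 4 matched days (10, 20, 30 and 60) 22 genes rose and 40 fell, array weights gave 1597 and a second quantile normalization put 45.4% of the called genes higher, against 58.1%. Of the genes named above, Nos3 (-0.03) and Csf3r (-0.07) turned sign on those days. The count moved by over 1.5 times without NT-3 tube rostral day 1 replicates 1 (604) and 3 (161), day 3 replicates 1 (219) and 2 (763), day 10 replicate 1 (530), day 30 replicates 2 (220) and 3 (225) and day 60 replicate 1 (214), lesion control rostral day 1 replicate 2 (174), day 3 replicate 1 (206), day 10 replicate 3 (230) and day 60 replicate 3 (224).

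Caudal, the NT-3 tube (21 arrays) against lesion control (21) raised 453 genes and lowered 717 of 11479. RT1-CE10 (1.49 ± 0.10) and the chemokine Cxcl2 (0.91 ± 0.10) rose, with C6 (0.89 ± 0.14), Igfbp3 (0.74 ± 0.15), heme oxygenase Hmox1 (0.70 ± 0.12) and arginase Arg1 (0.68 ± 0.10). Cytokine and chemokine genes rose in 9 of 18 (12 adjusted over the list alone) and fell in 1, the latter Cxcl13 (-0.93 ± 0.19) (camera adjusted p = 9.87e-08, adjusted p = 0.148 with an estimated correlation). Complement genes rose in 7 and fell in 1 of 8, C3 (-0.50 ± 0.09) down (camera adjusted p = 3e-05, adjusted p = 0.17 with an estimated correlation). Microglia and macrophage genes rose in 6 of 21 (9 adjusted over the list alone), with Cd14 (0.51 ± 0.09), and fell in 1 (camera adjusted p = 0.000194, adjusted p = 0.301 with an estimated correlation). Lysosome and lipid handling genes rose in 7 of 19 (13 adjusted over the list alone), lipid-droplet perilipin Plin2 (0.29 ± 0.06) and Fabp4 (0.71 ± 0.23) among them, reactive astrocyte genes in 4 of 13 (6 adjusted over the list alone), with Lcn2 (0.60 ± 0.17), and fibroblast and fibrillar matrix genes in 3 of 24 (5 adjusted over the list alone), with Postn (0.74 ± 0.17). The tests gave camera adjusted p = 5.98e-09, 0.000332 and 8.22e-05, and adjusted p = 0.195, 0.167 and 0.468 with an estimated correlation. Cholesterol synthesis genes fell in 10 of 16 (12 adjusted over the list alone), Idi1 (-0.24 ± 0.06) among them, oligodendrocyte and central myelin genes in 7 of 15 (10 adjusted over the list alone), with Mal (-0.27 ± 0.07), and homeostatic astrocyte genes in 7 of 12 (9 adjusted over the list alone), with Slc7a10 (-0.35 ± 0.07). The lists had camera adjusted p = 4.01e-07, 3.87e-06 and 7.71e-06, and adjusted p = 0.178, 0.22 and 0.174 with an estimated correlation. Here neuron genes fell in 4 of 19 (4 adjusted over the list alone), Nefh (-0.26 ± 0.04) among them, and motor neuron genes in 2 of 6 (5 adjusted over the list alone), with peripherin Prph (-0.26 ± 0.07). The list tests gave camera adjusted p = 0.000344 and 0.00258, and adjusted p = 0.403 and 0.204 with an estimated correlation. Hoxd9 (-0.89 ± 0.14), Klhdc7a (-0.43 ± 0.08), Akr1c19 (-0.37 ± 0.05) and Greb1 (-0.34 ± 0.07) fell. On the 4 matched days (10, 20, 30 and 60) 81 genes rose and 152 fell, and array weights gave 2989. The count moved by over 1.5 times without NT-3 tube caudal day 10 replicate 3 (760) and day 20 replicate 2 (683).

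With tube alone against lesion control in the rostral segment (20 and 21 arrays), matrix genes rose and neuronal genes fell. Periostin, Postn (1.34 ± 0.18, 2.53-fold), the retinol receptor Stra6 (1.29 ± 0.12), asporin Aspn (1.00 ± 0.27), collagen Col1a1 (0.93 ± 0.15), fibronectin Fn1 (0.81 ± 0.11) and the water channel Aqp1 (1.02 ± 0.16) rose. Fibroblast and fibrillar matrix genes rose in 22 of 24 (23 adjusted over the list alone) and cartilage and bone genes in 5 of 8, with Ibsp (1.07 ± 0.19). As lists they had camera adjusted p = 1.33e-17 and 0.000848, and adjusted p = 0.168 and 0.167 with an estimated correlation. Skeletal muscle genes moved with them, 11 of 15 (13 adjusted over the list alone) up, Myl1 (1.88 ± 0.44), Car3 (1.26 ± 0.32) and Klhl41 (1.03 ± 0.28) among the muscle transcripts. This list had camera adjusted p = 7.79e-07 and adjusted p = 0.301 with an estimated correlation. Immediate early genes rose in 7 of 9 (9 adjusted over the list alone), cytokine and chemokine genes in 10 of 20 (13 adjusted over the list alone), complement genes in 5 of 8 (7 adjusted over the list alone) and neutrophil genes in 5 of 9 (6 adjusted over the list alone), with S100a9 (1.05 ± 0.31). Here camera adjusted p was 1.05e-05, 1.05e-05, 1.75e-05 and 0.00308, and adjusted p = 0.184, 0.274, 0.142 and 0.356 with an estimated correlation. The cytokine list stood at 2.66 ± 1.04 on day 3, with 1 array at 3.84, against 1.43 ± 0.19, and at 1.54 ± 0.06 against 1.49 ± 0.06 on day 20. Endothelial Esm1 (0.91 ± 0.11) rose. Microglia and macrophage genes had a median of 0 and a mean of 0.02, 2 up and 4 down of 21 (camera adjusted p = 0.789, not called). All 19 neuron genes fell, Elavl4 (-0.42 ± 0.07) among them, synaptic transmission genes in 19 of 22 (20 adjusted over the list alone), with Gad1 (-0.38 ± 0.05), motor neuron genes in 5 of 7 and sensory ganglion genes in 5 of 8. For these lists camera adjusted p was 6.34e-11, 1.13e-10, 0.00735 and 0.00995, and adjusted p = 0.178, 0.142, 0.23 and 0.445 with an estimated correlation. Calcb (-0.48 ± 0.10), the synaptic Rab3c (-0.44 ± 0.08) and Cntnap2 (-0.43 ± 0.06), Cpne4 (-0.46 ± 0.07), Ano3 (-0.44 ± 0.06) and Abcd2 (-0.43 ± 0.07) fell. Cholesterol synthesis genes fell in 12 of 16 (14 adjusted over the list alone), oligodendrocyte and central myelin genes in 10 of 15 and neurotrophin and receptor genes in 4 of 7, Bdnf (-0.34 ± 0.06) and the NT-3 receptor Ntrk3 (-0.26 ± 0.06) among them. In this order camera adjusted p was 2.86e-05, 0.000442 and 0.0466, and adjusted p = 0.22, 0.301 and 0.28 with an estimated correlation. Of 11553 genes 1409 rose and 2116 fell, 18 and 0 at least 2-fold. On the 5 matched days (3, 10, 20, 30 and 90) 681 rose and 1194 fell. Days 1-3 alone gave 1893 genes (matrix genes rose in 0 of 24), days 10-90 2349, and array weights 5659. With the skeletal muscle list mean as a covariate Klhl41 had 0.00.

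Caudal, tube alone (21 arrays) against lesion control (21) raised 420 genes and lowered 573 of 11479. Stra6 (1.42 ± 0.17), Postn (1.04 ± 0.17), desmocollin Dsc2 (0.90 ± 0.15), Lilrb4 (0.75 ± 0.19), C6 (0.73 ± 0.14) and Sfrp4 (0.73 ± 0.13) rose. Fibroblast and fibrillar matrix genes rose in 16 of 24 (20 adjusted over the list alone), with Fn1 (0.63 ± 0.10), complement genes in 4 of 8 (5 adjusted over the list alone) and cytokine and chemokine genes in 3 of 18 (6 adjusted over the list alone). By the list test camera adjusted p was 4.23e-16, 3.66e-05 and 0.00179, and adjusted p = 0.169, 0.174 and 0.349 with an estimated correlation. Skeletal muscle genes, beside them, had 0 of 11 past the threshold (0 adjusted over the list alone), a median of 0.37 and camera adjusted p = 0.0166, adjusted p = 0.518 with an estimated correlation. Cholesterol synthesis genes fell in 6 of 16 (11 adjusted over the list alone), neuron genes in 5 of 19 (11 adjusted over the list alone) and Schwann cell and peripheral myelin genes in 3 of 8 (3 adjusted over the list alone), with Pmp2 (-0.62 ± 0.10). These had camera adjusted p = 4.51e-06, 9.66e-05 and 0.0364, and adjusted p = 0.218, 0.372 and 0.433 with an estimated correlation. Ciliary neurotrophic factor, Cntf (-0.29 ± 0.05), fell, as did chondromodulin Cnmd (-0.84 ± 0.13), Mlip (-0.64 ± 0.09), Hoxd9 (-0.63 ± 0.14), Hoxa10 (-0.43 ± 0.14) and myocilin Myoc (-0.44 ± 0.09). On the 5 matched days (3, 10, 20, 30 and 90) 347 genes rose and 455 fell, array weights gave 2853, and a second quantile normalization put 52.4% of the called genes higher, against 42.3%. The count moved by over 1.5 times without tube alone caudal day 1 replicate 3 (602) and day 3 replicate 1 (1534), lesion control caudal day 1 replicates 1 (616) and 3 (1503), day 3 replicate 3 (645) and day 20 replicate 2 (652).

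In the lesion segment on day 3, tube alone (3 arrays) against lesion control (3) lowered interferon and muscle genes. Of the interferon response genes 11 of 16 (12 adjusted over the list alone) fell, Isg15 (-2.64 ± 0.42), Mx1 (-2.16 ± 0.35), Ifit3 (-1.78 ± 0.35) and Oas1a (-1.67 ± 0.28) among them, beside the chemokine Cxcl10 (-1.21 ± 0.32). The list had camera adjusted p = 1.59e-12 and adjusted p = 0.0817 with an estimated correlation. Skeletal muscle genes fell in 4 of 16 (8 adjusted over the list alone), Myl1 (-4.74 ± 1.26), Acta1 (-4.71 ± 1.18), Tnnc2 (-4.07 ± 1.07), Myl11 (-3.96 ± 1.21) and sarcolipin Sln (-2.33 ± 0.73) among the muscle transcripts. The list test gave camera adjusted p = 0.000384 and adjusted p = 0.478 with an estimated correlation. The muscle list stood at 0.41, 4.36 and 1.44 in lesion control replicates 1 to 3 and between -0.19 and -0.14 in tube alone, so control replicate 2 held most of this difference. With the list mean as a covariate 154 genes passed. Lymphocyte genes fell in 2 of 13 (5 adjusted over the list alone), with Cd3g (-0.90 ± 0.24) (camera adjusted p = 0.178). Secretogranin, Scg2 (1.69 ± 0.54), cochlin Coch (1.55 ± 0.35), the complement regulator Cd55 (1.23 ± 0.30), Stra6 (1.16 ± 0.22), Slc6a20a (0.99 ± 0.17), Spetex2l1 (2.22 ± 0.20) and ceruloplasmin Cp (0.72 ± 0.14) rose. Of 19 neuron genes 1 rose, with a median of 0.51 (0 adjusted over the list alone, camera adjusted p = 0.0075, adjusted p = 0.617 with an estimated correlation). The neuron list stood at -2.49, -4.66 and -4.77 in control replicates 1 to 3 and between -3.51 and -3.46 in tube alone. Of 11922 genes 224 rose and 622 fell, 26.5% of the called genes higher against 55.3% after a second quantile normalization. Fitted with only its own groups the comparison called 0 genes by limma (2459 at unadjusted p under 0.05), and the count moved by over 1.5 times without tube alone lesion day 3 replicates 2 (432) and 3 (351), lesion control lesion day 3 replicates 1 (1984), 2 (325) and 3 (338).

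NT-3 tube against tube alone in the rostral segment (21 and 20 arrays) gave lower matrix and higher neuronal genes on average over all days, with the neuron list the other way on days 1 and 3. Fibroblast and fibrillar matrix genes fell in 23 of 24 (23 adjusted over the list alone), Col1a1 (-1.06 ± 0.15), Postn (-1.39 ± 0.18), Cthrc1 (-1.05 ± 0.12) and dermatopontin Dpt (-1.01 ± 0.12) among the matrix transcripts. This list had camera adjusted p = 1.36e-27 and adjusted p = 0.0711 with an estimated correlation. Skeletal muscle genes moved with them, 10 of 15 (11 adjusted over the list alone) down, with Myl1 (-1.98 ± 0.44), beside the muscle genes Klhl41 (-1.02 ± 0.28) and Ankrd1 (-0.94 ± 0.20), and cartilage and bone genes fell in 5 of 8, with Ibsp (-1.27 ± 0.19). The tests gave camera adjusted p = 1.11e-07 and 0.000412, and adjusted p = 0.275 and 0.142 with an estimated correlation. Immediate early genes fell in 4 of 9 (6 adjusted over the list alone), complement genes in 3 of 8 (4 adjusted over the list alone), with C1r (-0.42 ± 0.06), and endothelial Esm1 (-0.93 ± 0.11) fell. The lists had camera adjusted p = 3.79e-05 and 0.000106, and adjusted p = 0.211 and 0.169 with an estimated correlation. Neuron genes rose in 16 of 19 (17 adjusted over the list alone), with Nefh (0.35 ± 0.05), synaptic transmission genes in 17 of 22 (18 adjusted over the list alone), with Gad1 (0.36 ± 0.05), and motor neuron genes in 4 of 7 (5 adjusted over the list alone), with Chodl (0.56 ± 0.07) and choline acetyltransferase Chat (0.54 ± 0.07). The list tests gave camera adjusted p = 1.05e-07, 1.09e-07 and 0.000982, and adjusted p = 0.247, 0.195 and 0.169 with an estimated correlation. Urotensin Uts2 (0.60 ± 0.11), the receptor Trhr (0.48 ± 0.06), Gng13 (0.48 ± 0.13), Sorcs3 (0.33 ± 0.05), netrin-G1 Ntng1 (0.32 ± 0.05) and Hebp2 (0.36 ± 0.06) rose. Of 11553 genes 1798 rose and 871 fell, 67.4% of the called genes higher against 55.6% after a second quantile normalization. On the 5 matched days (1, 3, 10, 20 and 30) 250 rose and 238 fell. Days 1-3 alone gave 530 genes, with Gad1, Nefh, C1r and Esm1 of opposite sign. Pooled with tube alone against lesion control, 29 of 42 named genes were weaker. The neuron list stood at -0.96 ± 0.14 and -1.27 ± 0.35 against normal cord on days 1 and 3 with the NT-3 tube and at -0.67 ± 0.12 and -1.10 ± 0.23 in tube alone, and the matrix list on day 1 at 2.09 ± 0.17 and 1.83 ± 0.10. Over all days 1746 genes passed with the skeletal muscle list mean as a covariate.

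Caudal, NT-3 tube against tube alone (21 and 21 arrays) raised 225 genes and lowered 226 of 11479. Here microglia and macrophage genes rose in 3 of 21 (7 adjusted over the list alone), with Aif1 (0.26 ± 0.07) (camera adjusted p = 0.000412, adjusted p = 0.324 with an estimated correlation). The costimulator Cd86 (0.27 ± 0.06) and the lectin receptor Clec12a (0.26 ± 0.07) rose. Cytokine and chemokine genes rose in 3 of 18 (5 adjusted over the list alone), Cxcl2 (0.35 ± 0.10), Ccl3 (0.34 ± 0.10) and osteopontin Spp1 (0.35 ± 0.08), lysosome and lipid handling genes in 1 of 19 (6 adjusted over the list alone), lymphocyte genes in 1 of 7 (4 adjusted over the list alone) and MHC class II presentation genes in 1 of 9. As lists they had camera adjusted p = 0.0135, 0.000159, 0.00218 and 0.00426, and adjusted p = 0.439, 0.373, 0.218 and 0.301 with an estimated correlation. Lcn2 (0.57 ± 0.17), the replication gene Gins1 (0.31 ± 0.06), Tmem33 (0.26 ± 0.06) and the neurotrophic factor Cntf (0.25 ± 0.05) rose. Fibroblast and fibrillar matrix genes fell in 2 of 24 (9 adjusted over the list alone), with Ogn (-0.34 ± 0.09), and homeostatic astrocyte genes in 1 of 12 (5 adjusted over the list alone). Here camera adjusted p was 6.3e-06 and 0.00229, and adjusted p = 0.399 and 0.317 with an estimated correlation. Smooth muscle actin Actg2 (-0.34 ± 0.07), complement C3 (-0.39 ± 0.09), nexilin Nexn (-0.23 ± 0.06), the clock gene Per2 (-0.40 ± 0.08), Rapgef5 (-0.22 ± 0.05), Ube2o (-0.22 ± 0.06) and Tmtc1 (-0.22 ± 0.05) fell. Skeletal muscle genes had 0 of 11 past the threshold (0 adjusted over the list alone), a median of -0.31 and camera adjusted p = 0.00384, adjusted p = 0.433 with an estimated correlation. On the 4 matched days (1, 10, 20 and 30) 675 genes rose and 1022 fell, and the mean of all probe sets gave 289 genes, 62.6% higher against 49.9%. 0 genes passed at 2-fold by limma (2754 at unadjusted p under 0.05 without that limit), and the count moved by over 1.5 times without NT-3 tube caudal day 1 replicate 1 (273), day 3 replicate 3 (280), day 10 replicate 2 (699), day 20 replicate 2 (225), day 30 replicates 1 (276) and 2 (252), day 60 replicate 1 (278) and day 90 replicate 3 (237), tube alone caudal day 1 replicates 2 (1143) and 3 (160), day 3 replicates 1 (1022), 2 (274) and 3 (211), day 10 replicates 1 (233) and 3 (781), day 20 replicate 3 (203), day 60 replicate 2 (203) and day 90 replicate 3 (258).

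In the lesion segment on day 3, NT-3 tube against tube alone (3 and 3 arrays) gave lower phagocyte genes. Microglia and macrophage genes fell in 15 of 21 (17 adjusted over the list alone), Aif1 (-1.06 ± 0.22) and Cd68 (-0.92 ± 0.15) among them, beside the Fc receptor Fcgr3a (-1.39 ± 0.22), lysosome and lipid handling genes in 9 of 19 (10 adjusted over the list alone), Fabp4 (-1.10 ± 0.26) among them, beside the apolipoprotein Apoc1 (-1.53 ± 0.43), and MHC class II presentation genes in 6 of 9 (7 adjusted over the list alone), with RT1-DMa (-0.81 ± 0.15). For these lists camera adjusted p was 4.2e-10, 4.4e-08 and 7.96e-06, and adjusted p = 0.142, 0.142 and 0.142 with an estimated correlation. Lymphocyte genes fell in 3 of 13, with Cd8a (-1.17 ± 0.22) (camera adjusted p = 0.0263, adjusted p = 0.468 with an estimated correlation). Mmp12 (-1.88 ± 0.22), Ddx60 (-1.75 ± 0.35), Psca (-1.27 ± 0.20) and Spetex2l1 (-2.49 ± 0.20) fell. Cytokine and chemokine genes had a median of -0.05 and a mean of 0.13, with Il6 (1.53 ± 0.41) and Cxcl2 (1.19 ± 0.42) up and Ccl4 (-1.03 ± 0.25) down (camera adjusted p = 0.29, not called). Schwann cell and peripheral myelin genes rose in 5 of 9 (6 adjusted over the list alone), with Pmp2 (2.32 ± 0.26) and periaxin Prx (1.51 ± 0.33), and fell in 1. The list had camera adjusted p = 0.0333 and adjusted p = 0.391 with an estimated correlation. The sensory ganglion list moved with them, at 0.12, 1.52 and -0.27 in NT-3 tube replicates 1 to 3 and -0.64 ± 0.07 in tube alone (camera adjusted p = 0.109), and the neuron list stood at -2.91 ± 0.53 and -3.48 ± 0.03. Neurotrophin and receptor genes rose in 3 of 7 (4 adjusted over the list alone), Bdnf (0.84 ± 0.20), Cntf (1.74 ± 0.26) and Gfra1 (0.73 ± 0.14) (camera adjusted p = 0.101), fibroblast and fibrillar matrix genes in 5 of 24 (12 adjusted over the list alone) (camera adjusted p = 0.00256, adjusted p = 0.425 with an estimated correlation) and complement genes in 4, with Cfi (1.38 ± 0.23), while 1 fell (camera adjusted p = 0.0868, not called). Skeletal muscle genes moved with these, 4 of 16 (6 adjusted over the list alone) up, with Myl1 (4.63 ± 1.26), Acta1 (3.83 ± 1.18), Tnnc2 (3.70 ± 1.07) and Myl11 (3.53 ± 1.21). The list test gave camera adjusted p = 0.0173 and adjusted p = 0.649 with an estimated correlation. The muscle list stood at 0.58, 1.30 and 3.75 in NT-3 tube replicates 1 to 3, so replicate 3 held most of this rise. Mlip (2.63 ± 0.25) and synuclein gamma Sncg (2.43 ± 0.43) rose. Of 11922 genes 1906 rose and 891 fell, 68.1% of the called genes higher against 43.2% after a second quantile normalization, and array weights gave 4242. The RT1-CE10 means of these arms differed on this day (9.05 ± 1.12 and 7.77 ± 0.33).

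The NT-3 tube effect against lesion control in the lesion segment differed between days 60-90 (6 and 6 arrays) and day 3 (3 and 3) in 3400 genes by the interaction test, 1797 up and 1603 down of 11922. Values here are the later difference minus the earlier one. Lymphocyte genes were higher in 12 of 13, with Cd3d (2.21 ± 0.30), MHC class II presentation genes in 7 of 9, with RT1-Db1 (2.12 ± 0.29), microglia and macrophage genes in 12 of 21, interferon response genes in 10 of 16 and cell cycle genes in 11 of 21. In this order camera adjusted p was 4.77e-08, 8.56e-07, 4.11e-05, 6.3e-06 and 0.000358, and adjusted p = 0.142, 0.113, 0.274, 0.224 and 0.301 with an estimated correlation. Mmp12 (3.27 ± 0.27), Ccl9 (4.20 ± 0.53), Mmp3 (3.78 ± 0.68) and the immunoglobulin gene Ighl2 (4.61 ± 1.13) were higher. Neuron genes were lower in 17 of 19, with Stmn2 (-4.57 ± 0.82), all 9 sensory ganglion genes, with Prph (-4.58 ± 0.87), motor neuron genes in 6 of 7, oligodendrocyte and central myelin genes in 10 of 15 and Schwann cell and peripheral myelin genes in 5 of 9. By the list test camera adjusted p was 5.84e-11, 1.86e-07, 9.12e-06, 2.39e-05 and 0.00109, and adjusted p = 0.224, 0.221, 0.126, 0.374 and 0.22 with an estimated correlation. Neurotrophin and receptor genes were lower in 5 and higher in 1 of 7, Gfra1 (-1.54 ± 0.17) and Cntf (-2.17 ± 0.32) down (camera adjusted p = 0.0023, adjusted p = 0.195 with an estimated correlation). Skeletal muscle genes were lower in 3 of 16 (camera adjusted p = 0.000455, adjusted p = 0.483 with an estimated correlation). Counts adjusted over the list alone did not differ from these, except for MHC class II presentation genes (8 that rose), microglia and macrophage genes (14 that rose), cell cycle genes (14 that rose) and motor neuron genes (7 that fell). With the sensory ganglion list mean as a covariate 419 genes passed. RT1-CE10 of the arms differed by 1.20 on day 3 and 3.86 on day 90.

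In the rostral segment the same interaction, days 60-90 minus days 1-3 (6 and 6 later arrays), passed in 1991 genes, 1084 up and 907 down. Neuron genes were higher in 14 of 19 (16 adjusted over the list alone), with Thy1 (0.74 ± 0.15), synaptic transmission genes in 16 of 22, with Gad1 (0.74 ± 0.12), and homeostatic astrocyte genes in 5 of 12 (7 adjusted over the list alone). These had camera adjusted p = 6.65e-10, 4.84e-09 and 0.000811, and adjusted p = 0.195, 0.169 and 0.288 with an estimated correlation. Heat-shock Hspa1a (-2.04 ± 0.41), heme oxygenase Hmox1 (-1.58 ± 0.17) and Nos3 (-1.35 ± 0.19) were lower, with endothelium and angiogenesis genes in 5 of 20 (9 adjusted over the list alone). This list had camera adjusted p = 0.000361 and adjusted p = 0.233 with an estimated correlation. Array weights gave 3814 genes. RT1-CE10 of the arms differed by 4.08, 1.12 and 3.67 on days 1, 3 and 90.

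Caudal, that interaction passed in 113 genes, 41 up and 72 down of 11479. MHC class II presentation genes were higher in 2 of 9 (4 adjusted over the list alone), the invariant chain Cd74 (1.21 ± 0.29) among them, as was the lipid enzyme Lcat (1.28 ± 0.18), and Hspa1a (-1.97 ± 0.37), Cxcl2 (-1.77 ± 0.27), Arg1 (-1.19 ± 0.25) and the cystatin gene Stfa2l2 (-1.99 ± 0.33) were lower, with endothelium and angiogenesis genes in 3 of 20 (10 adjusted over the list alone). The tests gave camera adjusted p = 9.96e-07 and 9.17e-05, and adjusted p = 0.127 and 0.22 with an estimated correlation. RT1-CE10 differed by 3.87, 1.73 and 3.81 on days 1, 3 and 90. Array weights gave 2636 genes, and a second quantile normalization put 58.1% of the called genes higher, against 36.3%. The count moved by over 1.5 times without NT-3 tube caudal day 1 replicates 1 (46), 2 (207) and 3 (67), day 3 replicate 3 (62), day 60 replicates 1 (44) and 2 (191) and day 90 replicates 1 (62), 2 (59) and 3 (171), lesion control caudal day 3 replicates 1 (68) and 2 (58), day 60 replicate 3 (51) and day 90 replicates 1 (72) and 2 (58).

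The effect of the NT-3 tube against lesion control differed between the rostral and caudal segments in 9 of 11989 genes, 7 more positive rostral and 2 more negative (950 at unadjusted p under 0.05 by limma). Peripheral myelin Pmp2 (0.85 ± 0.13) and the motor neuron gene Chat (0.46 ± 0.10) were among the former. Fibroblast and fibrillar matrix genes had 0 of 24 past the threshold (2 adjusted over the list alone), a median of -0.21 and camera adjusted p = 3.77e-12, adjusted p = 0.218 with an estimated correlation. A second quantile normalization put 63.6% of the called genes higher, against 77.8%, array weights gave 139 genes, and the count moved by over 1.5 times without NT-3 tube caudal day 20 replicate 1 (14).

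Of 331 calls of gene lists over all comparisons, 20 held with an estimated correlation: microglia and macrophages in 5, reactive astrocytes in 9, cholesterol synthesis in 3, lysosome and lipid handling in 1, fibroblasts and fibrillar matrix in 1 and cytokines and chemokines in the lesion with the NT-3 tube.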

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

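The test of ganglion tissue and both tissue covariates were chosen only after the result was seen.

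4 results were differences between times or segments. The NT-3 tube effect differed between late and early days in 1991 rostral, 113 caudal and 3400 lesion genes, and between segments in 9 genes. The lesion genes named were Ighl2 (4.61 ± 1.13), Ccl9 (4.20 ± 0.53), Mmp3 (3.78 ± 0.68), Mmp12 (3.27 ± 0.27), Cd3d (2.21 ± 0.30), RT1-Db1 (2.12 ± 0.29), Gfra1 (-1.54 ± 0.17), Cntf (-2.17 ± 0.32), Stmn2 (-4.57 ± 0.82) and Prph (-4.58 ± 0.87). Rostral they were Gad1 (0.74 ± 0.12), Thy1 (0.74 ± 0.15), Nos3 (-1.35 ± 0.19), Hmox1 (-1.58 ± 0.17) and Hspa1a (-2.04 ± 0.41), caudal Lcat (1.28 ± 0.18), Cd74 (1.21 ± 0.29), Arg1 (-1.19 ± 0.25), Cxcl2 (-1.77 ± 0.27), Hspa1a (-1.97 ± 0.37) and Stfa2l2 (-1.99 ± 0.33), and between segments Pmp2 (0.85 ± 0.13) and Chat (0.46 ± 0.10). Over 100 splits of the same arrays chance was excluded rostral (1 split as high, highest other 1248). In the lesion (2, highest other 3462) and caudal (3, 1161) another split called more genes, so chance stays open. Between segments chance was not excluded either (6 splits as high, highest other 1592). Whether a structure of the samples lies behind such splits was not tested.

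Skeletal muscle genes were lower with the NT-3 tube than in lesion control lesion segments. Muscle tissue in the control segments would lower muscle genes outside the list as well, and 28 of 29 (96.6%) were lower, with a median of -1.62. Only 3 of the 16 list members and 8 of these 29 reached the dim threshold in normal cord, which is consistent with muscle in the control samples. With quantiles already alike, a second quantile normalization (median -1.97, -2.01 before) cannot test scaling. No biological explanation was tested, so regrowth of muscle into an open gap remains possible.

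Neuronal genes fell in the same comparison. As the whole cause, sensory ganglion tissue in the control segments predicts unchanged genes of cord neurons: 6 tested ones had a median of -0.23, from -0.90 to 0.08, and 2 were lower, which leaves it open. With the ganglion list mean as a covariate the neuron median was -0.22, but 6 of the 9 list members reached the dim threshold in normal cord, so this covariate takes out cord signal too and decides nothing. Ganglion tissue and more cord tissue in the control segments both stay open. More spared cord in 1 control array of day 3 is argued against by days without that array: the neuron list stood at -4.45 ± 0.15 and -3.82 ± 0.48 on days 20 and 90 with the NT-3 tube and at -1.96 ± 0.20 and -1.73 ± 0.33 in lesion control. The median of -1.55 without day 3 adds nothing, since day 3 ran the other way. No biological explanation was tested.

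Matrix genes rose and neuronal genes fell rostral with tube alone. Lesion tissue in those segments predicts the same of genes outside the lists: 764 of 777 lesion-high genes (98.3%) were higher in tube alone, against 44.6% of all genes, and 1104 of 1116 lesion-low genes were lower. A segment taken nearer the gap, or scar reaching further rostral, could both give this and the tables do not tell them apart. A median of 0.59 after a second normalization tests scaling no better. By days, the matrix median was 0.30 on days 1-3 (0 of 24 rose) and 0.68 on days 10-90 (24 rose).

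Among the 5 reference arrays replicate 5 lay farthest from the others, with a gap over range of 0.738 against a critical 0.71. Only 1 group was tested, and such a rule marks about 1 group in 20 by chance. Without it the technical SD was 0.092 instead of 0.121.

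For the remaining counts only the real split was as high (1 of 84 or 100), a share under 0.05: lesion control against normal gave 6817, 7286 and 6693 rostral (highest other 5854, 5142 and 4946), 9288 and 8608 in the lesion from day 10 (6669 and 7230) and 7029, 6581 and 6060 caudal (6691, 4429 and 5005). The same held for NT-3 tube against lesion control caudal (1170, highest other 431) and in the lesion (5011, 515), tube alone against lesion control rostral (3525, 1492) and caudal (993, 17) and NT-3 tube against tube alone rostral (2669, 6). NT-3 tube against lesion control rostral (351, highest other 1067) and against tube alone caudal (451, 1689) had 2 splits as high, also under 0.05. Another split called more in each, so chance stays open. On day 3 in the lesion 10 splits were too few: 9188 (highest other 775), 846 (229) and 2797 (2).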

How the results depend on the processing

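The comparisons over part of the days, with tissue covariates and on days with RT1-CE10 alike were chosen only after the result was seen. The counts were the same (within 1.5 times) in 22 of 22 comparisons without the filter and with an intensity trend and robust prior, 20 with a second quantile normalization, 18 with only the groups in the contrast, 21 with the mean of all probe sets and 11 with array weights, where the cause was not tested and the weights did not always converge. The labels do not say that array numbers mark pairs, so the same counts with the replicate block (22 of 22) do not settle pairing. Residuals of equal numbers had median correlations of 0.10 rostral, -0.04 in the lesion and 0.03 caudal between arms. Between segments of one arm and day it was 0.06 (-0.01 for unequal numbers). Not every pair was over 0.1 (49.2%, 30.4%, 30.2% and 46.4%).

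Array weights gave 1597, 2989 and 139 genes for NT-3 tube against lesion control rostral, caudal and between segments, 3814, 2636 and 5292 for its late minus early effect rostral, caudal and in the lesion, 5659, 2853 and 3946 for tube alone against lesion control rostral, caudal and in the lesion, and 1855 and 4242 for NT-3 tube against tube alone caudal and in the lesion. A second quantile normalization gave 526 for tube alone in the lesion and 708 for NT-3 tube against tube alone caudal, where the mean of all probe sets gave 289. With only the groups in the contrast these were 0 (2459 at unadjusted p under 0.05 by limma) and 180, and NT-3 tube against tube alone in the lesion had 1860 and NT-3 tube between segments 14. The cause was not tested. At 2-fold or more, lesion control against normal had 1007, 1443 and 1088 genes rostral, 4405, 3752 and 3149 in the lesion and 1211, 970 and 740 caudal. NT-3 tube against lesion control had 1 rostral, 1 caudal, 215 in the lesion, 49, 20 and 912 late minus early and 0 between segments. Tube alone had 18, 3 and 58, and NT-3 tube against tube alone 26, 0 and 210.

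On days with RT1-CE10 alike, NT-3 tube against lesion control had 62 rostral and 233 caudal, tube alone 1875 rostral, and NT-3 tube against tube alone 488 rostral and 1697 caudal, and 2 of 7 counts were the same. Choices of as many days gave medians of 174, 452, 2876, 1987 and 111. Days 1-3 and 10-90 gave 1893 and 2349 for tube alone rostral, and days 1-3 530 for NT-3 tube against it. The muscle covariate gave 1746 in the latter and 154 for tube alone in the lesion, the ganglion covariate 2130 for NT-3 tube in the lesion and 419 for its late minus early effect. Of 331 list calls 20 held with an estimated correlation. The sign turned for Csf3r (-0.07) and Nos3 (-0.03) on days with RT1-CE10 alike, Klhl41 (0.00) in tube alone with the muscle covariate, and C1r (0.03), Esm1 (0.07), Gad1 (-0.13) and Nefh (-0.08) in NT-3 tube against tube alone on days 1-3.

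Leaving out each array in turn, counts were the same in 477 of 535 fits. They ranged over 161 to 763 (NT-3 tube against lesion control rostral), 683 to 1642 (caudal), 602 to 1534 (tube alone caudal), 325 to 1984 (tube alone lesion), 160 to 1143 (NT-3 tube against tube alone caudal), 44 to 207 (late minus early caudal) and 9 to 14 (between segments). Where tube alone rostral on day 10 keeps 1 array, that array is assumed to vary like the others.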

Other observations

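The comparison on days with RT1-CE10 alike was chosen only after the result was seen.

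In the lesion segment the immune genes of the NT-3 tube arm were at high levels on day 20, when RT1-CE10 differed by 2.58 between the arms there. The cytokine and chemokine list stood at 3.93 ± 0.21 log2 above normal cord (SD, n = 3), against 1.86 ± 0.05 in lesion control, and the lymphocyte list at 2.72 ± 0.27 against 1.25 ± 0.06. Cxcl13, the chemokine of B-cell follicles, was at 12.99 ± 0.29 against 9.29 ± 0.25, and Mmp3 at 11.85 ± 0.70 against 6.96 ± 0.37. Other tissue differed as well: the muscle list stood at 0.37 ± 0.69 against 3.92 ± 0.70, the ganglion list at -1.23 ± 0.03 against 2.09 ± 0.44 and the neuron list at -4.45 ± 0.15 against -1.96 ± 0.20. The immunoglobulin heavy chain gene Ighl2 was at 11.12 ± 0.57 and 11.21 ± 0.70 on days 60 and 90 with the NT-3 tube, and at 7.06 ± 1.24 and 6.30 ± 0.32 in lesion control, days on which RT1-CE10 differed by 0.15 and 3.86 between the arms.

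The division of groups by RT1-CE10 is the pattern most worth following up. On matched days the rostral difference of NT-3 tube and tube alone had 488 genes against 2669 on all days, and 2 of 21 choices of 5 days gave as few, while caudal it had 1697 against 451 and 5 of 35 choices of 4 days gave as many. For NT-3 tube against lesion control 11 of 35 choices gave as few as 62 rostral and 8 of 35 as few as 233 caudal, and for tube alone 2 of 21 as few as 1875 rostral and 15 of 21 as few as 802 caudal. In the lesion 3606 genes passed against 5011 on all days, and 9 of 20 choices of 3 days gave as few. What divides the groups was not tested.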
